A study of Homo sapiens with 20 samples.

How the data were processed

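RNA of U-87MG cells treated for 24 h with I3P, HPP or PP at 40 µM, or with DMSO (at most 0.2%), was measured on 20 Affymetrix arrays, 5 per group. The values used were the series matrix's deposited log2 expression values, made by the authors with the package oligo and RMA, which corrects background, normalises quantiles between arrays and summarises probes to probe sets, per the submitters' processing notes. The versions of oligo, RMA and the probe set annotation are not given in the sources used here. The table held 12770 probe sets with values between 5.506 and 14.16, and no probe set had a mean over the arrays below 7.943, which points to a filter on dim probe sets that the sources used here do not state. Genes of low signal are therefore outside what could be tested, and a change on the RMA scale can understate the true change of dim genes. The number of arrays limits the stated precision. Each column was matched to its sample by the sample identifier in its header, no column of values was left unused, and no array was left out.

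Probe sets were named from the platform annotation, with symbols updated through the RefSeq gene table of the human assembly GRCh38.p14, used for names only. Of the probe sets, 11316 had a single symbol, 629 several and 825 none. The symbol was updated for 833 and kept as given for 33 that had no match. Probe sets with no symbol or several were left out of the tests of named genes. For the 33 genes with more than 1 probe set, the one with the highest mean over all arrays was kept, which left 11282 genes.

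Group means were fitted to all 20 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the groups share an estimate of the spread per gene. The 6 comparisons were each compound against DMSO and each pair of compounds, 2-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05 on the adjusted p. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The groups, comparisons, tests, gene lists, rule for named genes and all alternatives not said to be added later were fixed before the data were examined, with the fit without the replicate block as the main test.

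The labels give each group replicate numbers 1 to 5, and whether these pair the arrays was checked from the correlation of the arrays' deviations from their group means. All 30 pairs of arrays with the same number correlated above 0.1 (0.163 to 0.714, median 0.43), the 120 pairs with different numbers had a median of -0.157 and a highest of 0.378, and 19 of 20 arrays correlated best with an array of their own number. Arrays of number 1 correlated with those of number 2 at 0.186 to 0.378, against 0.163 to 0.395 within number 2, so these numbers are poorly told apart. The number took up a median of 54% of a gene's sum of squares within groups, where 25% is expected with no such effect. The numbers were therefore taken to pair the arrays, and the fit with the number as a fixed block (12 residual degrees of freedom in place of 16) is given beside each result that it changes.

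Named genes were, for each compound against DMSO, the 10 largest rises and the 10 largest falls among genes past the threshold with all 5 treated arrays on the same side of the DMSO mean. All measured AHR target genes were added, with 2 to 4 called members per list with the largest change, or the 2 with the smallest p where none was called. For each pair of compounds the 5 largest in each direction were taken. Where no gene passed, the 3 with the smallest p were named and said not to pass, and AHR, ARNT and IL4I1 were always to be given. The same rule was applied to the fit with the block after the data had been seen. Other genes named are said to be chosen after their values were seen.

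The 17 gene lists covered AHR target genes, the AHR complex, catabolism of tryptophan, tyrosine and phenylalanine, NRF2 target genes, the ATF4 and amino acid response, endoplasmic reticulum chaperones, cholesterol synthesis, hypoxia and glycolysis, the cell cycle and p53 target genes. They further covered the interferon response, NF-kB and cytokines, extracellular matrix and TGF-beta response, immediate early and ERK response, the respiratory chain, markers of blood and microglial cells, and markers of epithelial, neuronal and oligodendrocyte cells. NQO1 (AHR and NRF2) and SLC7A11 (NRF2 and ATF4) were the 2 genes held by more than 1 list. Each list was tested against all other genes with camera (preset correlation 0.01), adjusted over the 17 lists of a comparison, and again with the correlation estimated from the data. Means of a list are given over the 5 same-number pairs with the SD and a 95% interval. An exact sign-flip test of 5 pairs cannot go below 0.0625.

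Alternatives were the replicate block, only the 10 arrays of the groups compared, cyclic loess, equal array medians, only genes above the median or the 25th percentile of level, all probe sets, and the mean over a gene's probe sets. Further ones were a trended and robust variance (for camera, a trended one only), array weights, an adjusted p under 0.01, a fold over 1.5, fry (a test of a list against no change) in place of camera, and each array left out in turn. Added after the data were seen were the same alternatives with the block, the number as a random block, fits without the arrays of number 3 or 5, camera with the block and an estimated correlation, list tests without given members, responses compared with no array or number shared, and a simulation of the split of DMSO arrays with no change. For it, 100 sets of arrays had the spread per gene of the fit with the block and its deviations per replicate number, multiplied by 0.891 to allow for the noise in them. The simulated noise was drawn independently for each gene.

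The code was tested on simulated data with the spread per gene and the replicate numbers' deviations of these arrays. With simulated changes in I3P against DMSO (11282 genes, 50 per fold), the fit without the block recovered 14% of genes changed 1.25-fold, 78% at 1.5-fold, 96% at 2-fold and 98% at 3-fold, and the fit with the block recovered 50%, 96%, 98% and 100%. Of the 11082 unchanged genes, 1 was called without the block and 14 with it. In this 1 simulation that is 0.7% of 144 calls and 7.5% of 186, the second above the 5% that the threshold aims at. A simulated list raised by 0.3 in log2 passed camera in both fits (adjusted p = 2.89e-15 and 4.19e-18) with 0 of the 16 other lists past the threshold. The simulated noise was independent between genes, so this does not measure false calls of lists whose members vary together.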

Results

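Gene expression was measured on Affymetrix arrays in U-87MG cells, an established human glioblastoma line, after 24 h with an aromatic alpha-keto acid at 40 µM or with the solvent DMSO alone. The 3 compounds were I3P (indole-3-pyruvic acid), HPP (hydroxyphenylpyruvic acid) and PP (phenylpyruvic acid). They are the keto acids of the amino acids tryptophan, tyrosine and phenylalanine. I3P carries an indole ring, PP a phenyl ring, and HPP a phenyl ring with a hydroxyl group. The series is about activation of the aryl hydrocarbon receptor (AHR), a transcription factor switched on by small molecules. The questions were which AHR target genes each compound changed and how the compounds differed at the same dose and time.

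Each of the 4 groups held 5 arrays, which the labels call biological replicates 1 to 5, and the 20 array medians lay between 9.23 and 9.279 on the log2 scale of the robust multi-array average (RMA). No pair of arrays held identical values. The number of arrays limits the precision, and each p-value sets a difference against an error estimated from the spread between these samples. For each of 11282 genes the difference between 2 groups was tested with limma, without and with the replicate number as a block, because arrays of the same number deviated together. The block leaves every log2 difference as it is and changes only its error, with a median standard error of 0.107 without it and 0.0789 with it. The error with the block leaves out the spread between replicate numbers.

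I3P raised known AHR target genes. TIPARP, an ADP-ribosyltransferase that is induced by AHR and restrains it, was at 11.06 ± 0.26 with I3P and 10.03 ± 0.17 with DMSO (log2, SD, n = 5), a 2.04-fold rise (log2 1.03, SE 0.17, adjusted p = 0.0234). CYP1B1, a cytochrome P450 enzyme that oxidises steroids and aromatic hydrocarbons, rose 1.72-fold, from 10.62 ± 0.25 to 11.41 ± 0.062 (adjusted p = 0.0339). STC2, which encodes a secreted glycoprotein, rose 1.74-fold (SE 0.145 in log2, adjusted p = 0.036). SECTM1, a secreted and transmembrane protein, rose 1.92-fold (log2 0.94, SE 0.169, adjusted p = 0.036), and PRDM1, the transcriptional repressor BLIMP-1, rose 1.59-fold (log2 0.67, SE 0.127, adjusted p = 0.0472). The other genes that passed without the block were LOXL3, of the lysyl oxidase family, LACC1, SNX9, a sorting nexin of endocytosis, and CARD10, an adaptor of NF-kB signalling, each higher by 1.33-fold to 1.43-fold. For all 9 genes every I3P array lay above every DMSO array.

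With the replicate block, 55 genes rose and 13 fell with I3P, every one of them in the same direction in all 5 same-number pairs. That agreement largely follows from selection by this fit and is no separate support. The largest rise was that of SLC16A6, a member of the monocarboxylate transporter family, at 2.95-fold (log2 1.56). Its SE was 0.091 with the block and 0.458 without it, and its adjusted p 7.09e-08 and 0.596. SERPINB2, an inhibitor of urokinase on the AHR target list, rose 2.40-fold (adjusted p = 1.31e-05 with the block, 0.711 without it). THBS1, the matrix glycoprotein thrombospondin, rose 2.28-fold (adjusted p = 4.02e-06, 0.369 without it). AHRR, the repressor that AHR itself induces, rose by 0.71 in log2 (adjusted p = 0.000198, 0.164 without it). Among the rises were also the citrate transporter SLC13A5 (log2 0.83) and SLC35F4 (0.73). The largest fall was in RGS4, a regulator of G protein signalling, which fell by 0.93 in log2 (adjusted p = 0.000664). The carboxypeptidase CPA4 fell by 0.57, MEST by 0.55, the potassium channel subunit ABCC9 by 0.42 and FJX1 by 0.41. In the same units the AMPK subunit PRKAG2 fell by 0.37, NOV by 0.35, the autophagy protease ATG4C by 0.32 and the transcription factor MECOM by 0.295.

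In all, 9 genes rose and 0 fell without the block, at folds of 1.33 to 2.04, and 509 genes had an unadjusted p under 0.05 without the block and 1243 with it, where 564 are expected by chance. The count without the block was 0 when DMSO replicate 2 or 5 or I3P replicate 2 or 4 was left out, 1 without DMSO replicate 4 and 2 without I3P replicate 1. It was 3 without DMSO replicate 1, I3P replicate 3, HPP replicate 4 or PP replicate 4, 4 without DMSO replicate 3 and 5 without I3P replicate 5. The 68 calls with the block, which held all 9, became 44 without DMSO replicate 5, 38 with the number as a random block, 37 without the arrays of number 5 (both added after the data were seen) and 20 when only the 10 arrays of these groups were fitted.

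Of the 12 measured members of the AHR target list, 11 were above DMSO with I3P, 3 rose without the block and 6 adjusted over the list alone. With the block 6 rose by either adjustment. They were TIPARP, SERPINB2, CYP1B1, STC2, AHRR and EREG, an epidermal growth factor receptor ligand (log2 0.46, adjusted p = 0.0186). The mean of the list was higher by 0.48 ± 0.11 (log2, SD over 5 same-number pairs, 95% interval 0.35 to 0.61, higher in 5 of 5). Camera gave an adjusted p of 6.34e-14, and 5.86e-06 with an estimated correlation. The members that did not pass were at 0.24 for ALDH3A1, 0.23 for the efflux transporter ABCG2, 0.15 for NFE2L2, 0.12 for the quinone reductase NQO1, 0.03 for the amino acid transporter SLC7A5 and -0.08 for CYP1A2. The receptor gene AHR itself was at -0.08 (adjusted p = 0.999) and its partner ARNT at -0.045 (adjusted p = 0.999). CYP1A1, UGT1A6 and IL4I1, the enzyme that makes these keto acids from amino acids, were not analysed here.

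**Figure D1:**
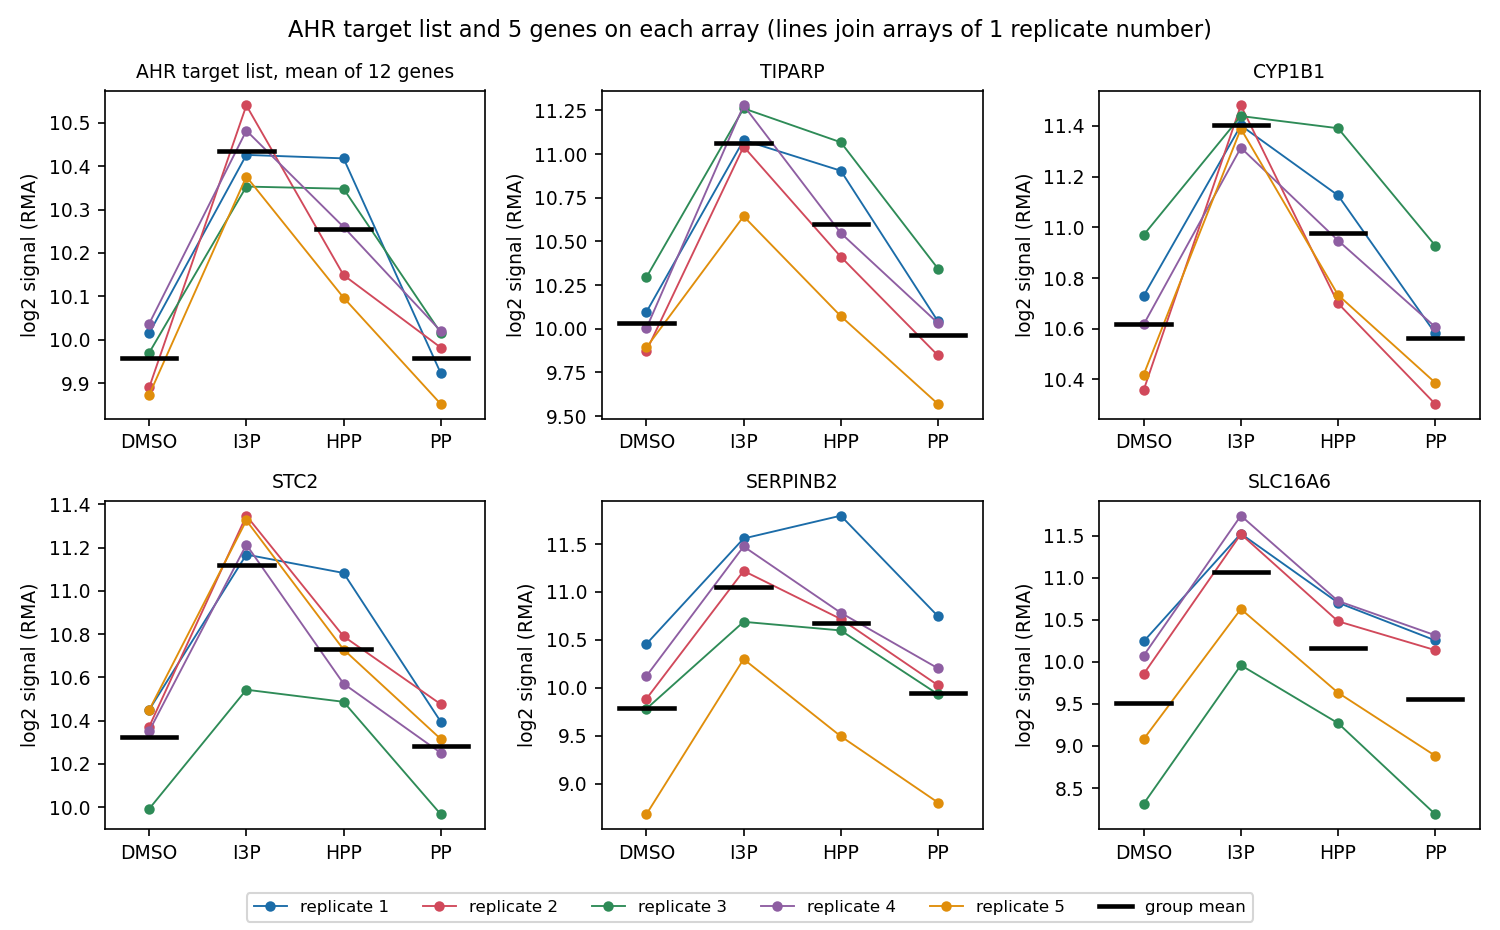
Each panel shows log2 signal (RMA) on the vertical axis and the 4 groups on the horizontal axis, with a point per array, lines joining arrays of the same replicate number and black bars at the group means. The mean of the 12 measured AHR target genes, TIPARP, CYP1B1, STC2, SERPINB2 and SLC16A6 are shown, and the mean log2 change of the list was 0.48 with I3P, 0.30 with HPP and 0.002 with PP.

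Genes of the NF-kB and cytokine list were higher with I3P. All 12 measured members were above DMSO, by 0.31 ± 0.024 on average (log2, SD over 5 pairs, 95% interval 0.28 to 0.34, higher in 5 of 5). With the block 3 members rose, namely IL1B, the cytokine interleukin-1 beta (log2 0.89, adjusted p = 0.000793), PTGS2, the inducible cyclooxygenase (0.66, adjusted p = 0.00373), and LIF, a cytokine of the interleukin-6 family (0.515, adjusted p = 0.000846). Adjusted over the list alone 6 rose. Without the block 0 of the 12 passed by either adjustment, in a fit where 509 genes had an unadjusted p under 0.05. The list passed camera without the block (adjusted p = 0.0171) but not with an estimated correlation (adjusted p = 0.818). It passed with the block in both forms (adjusted p = 2.19e-09, and adjusted p = 0.00198 with an estimated correlation). Without the block the adjusted p became 0.639 when DMSO replicate 3 was left out, 0.111 without I3P replicate 1, 0.108 without I3P replicate 2 and 0.0677 without I3P replicate 4.

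**Figure D2:**
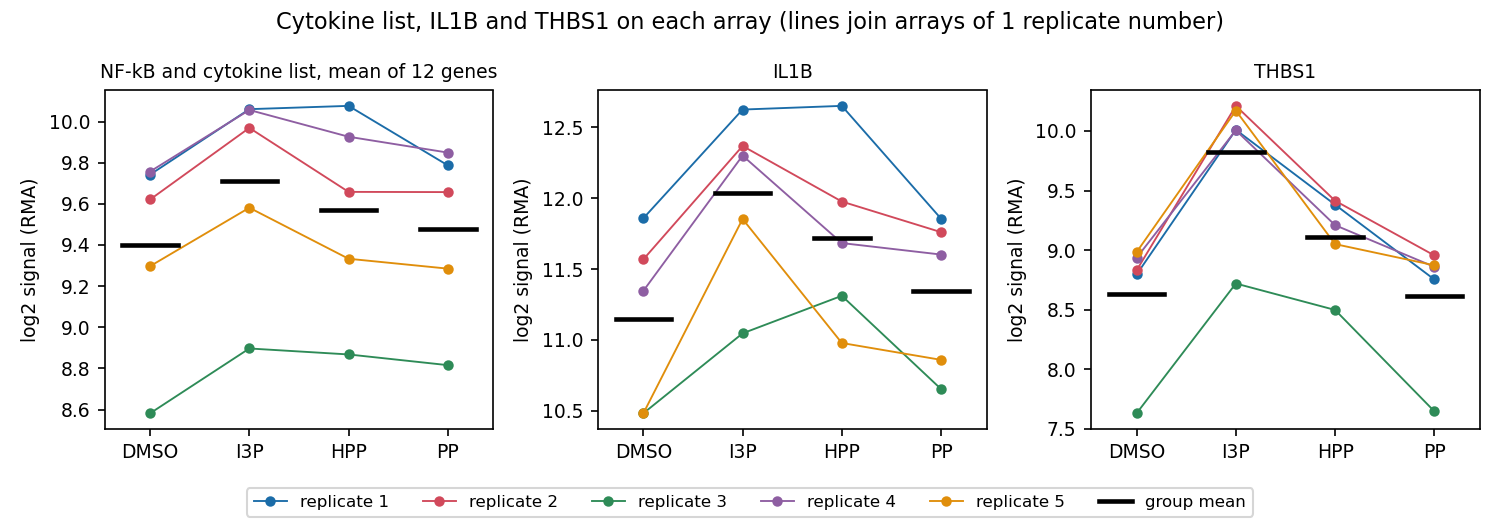
The 3 panels show log2 signal (RMA) per array against group for the mean of the 12 measured NF-kB and cytokine genes, for IL1B and for THBS1, with lines joining arrays of the same replicate number and black bars at the group means. Arrays of replicate number 3 lie lowest in the panels of the list and of THBS1, and the list was higher with I3P than with DMSO in 5 of 5 same-number pairs.

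Cell cycle genes were slightly lower with I3P, with 20 of 24 members below DMSO and a mean of -0.062 ± 0.032 (log2, SD, n = 5 pairs, 95% interval -0.10 to -0.023, lower in 5 of 5). None of the 24 passed by either adjustment in either fit, and CCNB2, a cyclin of mitosis, was at -0.28 (adjusted p = 0.628). The list passed camera (adjusted p = 0.0171) but not with an estimated correlation (adjusted p = 0.818), nor with the block and an estimated correlation (adjusted p = 0.395). The adjusted p was 0.639 without DMSO replicate 3, 0.111 without I3P replicate 1 and 0.562 without I3P replicate 5. Hypoxia and glycolysis genes passed only with the block (adjusted p = 0.126 without it and 0.0205 with it, and adjusted p = 0.479 with the block and an estimated correlation). Their mean was 0.074 above DMSO, higher in 5 of 5 pairs, and of 19 members the hexokinase HK2 rose with the block (log2 0.42, adjusted p = 0.00087, and 0.0544 without it).

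The remaining lists did not pass with I3P in either fit. By camera without the block the adjusted p was 0.841 for the AHR complex, 0.87 for tryptophan, tyrosine and phenylalanine catabolism (13 of 26 members measured), 0.87 for NRF2 target genes and 0.518 for the ATF4 and amino acid response. It was 0.439 for endoplasmic reticulum chaperones, 0.87 for cholesterol synthesis, 0.87 for p53 target genes, 0.277 for the interferon response and 0.518 for extracellular matrix and TGF-beta response genes. It was 0.542 for immediate early and ERK response genes, 0.518 for the respiratory chain, and 0.568 each for blood and microglial markers (4 measured) and for epithelial, neuronal and oligodendrocyte markers (5 measured). Single members of these lists rose or fell with the block, namely INSIG1, which retains the sterol sensor in the endoplasmic reticulum (log2 0.41, adjusted p = 0.000493), THBS1, and the transcription factor MYC, which fell by 0.31 (adjusted p = 0.00785).

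HPP raised a smaller set of genes, and with the replicate block I3P raised each of them too. With the block 5 genes rose against DMSO. They were SERPINB2 (1.86-fold, log2 0.89, adjusted p = 0.00667), SLC16A6 (1.57-fold, adjusted p = 0.0116) and TIPARP (1.48-fold, log2 0.57, adjusted p = 0.0128), with SCG5, a secretory granule chaperone (1.35-fold, adjusted p = 0.0127), and the collagenase MMP1 (1.295-fold, adjusted p = 0.028). SLC16A6 and MMP1 were named after their values were seen. By limma 161 genes had an unadjusted p under 0.05 without the block and 561 with it. As 564 are expected by chance, neither count exceeds chance. Without the block 0 genes passed limma's test, and each of the 5 had an adjusted p of 1. The genes with the smallest p there, which did not pass, were TTC39B at 0.295 (SE 0.081), CARD10 at 0.22 and the class II transactivator CIITA at 0.24 (adjusted p = 1). The 5 calls with the block became 1 without DMSO replicate 2 or 4, 2 without HPP replicate 1 or 3 and 3 without DMSO replicate 1 or HPP replicate 4. They became 2 without the arrays of number 5, 0 without those of number 3, 0 with the number as a random block (all 3 added after the data were seen) and 0 when only the 10 arrays of these groups were fitted.

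As a group, AHR target genes were higher with HPP, with 10 of 12 members above DMSO and a mean of 0.30 ± 0.087 (log2, SD over 5 same-number pairs, 95% interval 0.19 to 0.41, higher in 5 of 5). Camera gave an adjusted p of 3.07e-10, and 4.37e-05 with an estimated correlation. Over all genes 0 members passed without the block and 4 passed adjusted over the list alone, and with the block these counts were 2 (TIPARP and SERPINB2) and 8. The other members were at 0.42 for AHRR, 0.41 for STC2, 0.38 for EREG, 0.36 for CYP1B1, 0.23 for NQO1, 0.21 for ALDH3A1, 0.19 for SLC7A5, 0.07 for ABCG2, -0.01 for NFE2L2 and -0.15 for CYP1A2. AHR was at -0.07 and ARNT at 0.04, and neither passed.

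NRF2 target genes, which encode enzymes of glutathione and thioredoxin metabolism and other oxidant defences, were also higher with HPP. Of 16 members 15 were above DMSO, by 0.12 ± 0.070 on average (log2, SD over 5 pairs, 95% interval 0.028 to 0.20, higher in 5 of 5). The cystine transporter SLC7A11 was at 0.38 (adjusted p = 0.646 with the block) and the thioredoxin reductase TXNRD1 at 0.35 (adjusted p = 0.253 with the block). The list passed camera with an adjusted p of 1.9e-05, but not with an estimated correlation (adjusted p = 0.0642). It had an adjusted p = 0.0268 with the block and an estimated correlation. No member passed over all genes in either fit, and adjusted over the list alone 0 passed without the block and 3 with it. NQO1 is shared with the AHR target list and SLC7A11 with the ATF4 list.

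Cytokine genes had a mean of 0.17 with HPP (95% interval 0 to 0.34, higher in 5 of 5 pairs), with 8 of 12 members above DMSO. That list passed only with the block (adjusted p = 0.23 without it, 0.000102 with it, and adjusted p = 0.0268 with the block and an estimated correlation). IL1B was at 0.57 and PTGS2 at 0.56, and 0 members passed over all genes while 4 did with the block adjusted over the list alone. The ATF4 and amino acid response list passed only with the block (adjusted p = 0.181 without it, 0.0354 with it, and adjusted p = 0.631 with the block and an estimated correlation), at a mean of 0.048, above DMSO in 4 of 5 pairs. No other list passed with HPP in either fit. Camera's adjusted p without the block was 0.955 for the cell cycle, 0.897 for the respiratory chain and 0.897 for the extracellular matrix. It was 0.9 for cholesterol synthesis, 0.972 for blood and microglial markers, 0.897 for the epithelial and neuronal markers and 0.686 for the interferon response. For catabolism of the 3 amino acids it was 0.536, and for each of the AHR complex, chaperones, hypoxia, p53 and immediate early lists it was 0.578.

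PP gave no call. By limma 0 genes passed in either fit. An unadjusted p under 0.05 was held by 174 genes without the block and 479 with it, where 564 are expected by chance. AHR target genes had a mean difference from DMSO of 0.002 ± 0.070 (log2, SD over 5 pairs, 95% interval -0.085 to 0.089). Of their 12 members 5 were above DMSO and 0 passed by either adjustment, with a median of -0.02 and a camera adjusted p of 0.965 (direction down). TIPARP was at -0.065 (95% interval with the block -0.25 to 0.12), CYP1B1 at -0.06 (-0.24 to 0.12), and STC2 at -0.04 (-0.21 to 0.13). With the same intervals AHRR was at 0.11 (-0.068 to 0.29), SERPINB2 at 0.16 (-0.084 to 0.40) and SLC16A6 at 0.04 (-0.15 to 0.24). AHR was at 0.01 and ARNT at 0.00. The genes with the smallest p, which did not pass, were CATSPERQ at 0.395, TTC39B at 0.28 and the condensin subunit NCAPH2 at 0.23 (adjusted p = 1). Of the 17 lists 0 passed in either fit, and camera's smallest adjusted p without the block was 0.0966, for the respiratory chain (mean 0.051, higher in 5 of 5 pairs).

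**Figure D3:**
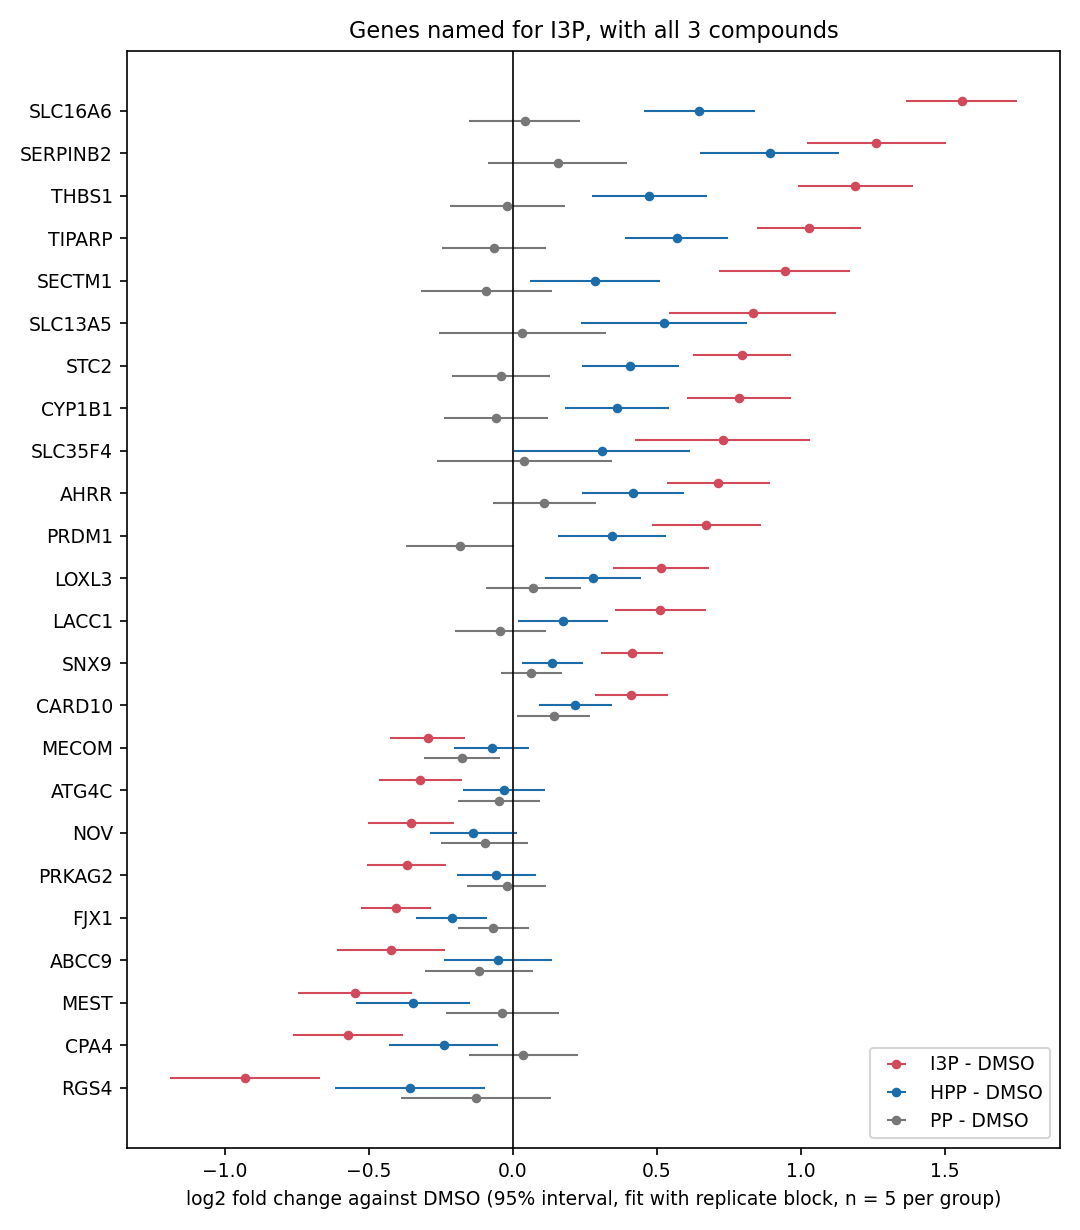
Points show log2 change against DMSO (horizontal axis) for 24 genes named for I3P (vertical axis), with I3P, HPP and PP in separate colours and bars giving 95% intervals from the fit with the replicate block. TIPARP lies at 1.03 with I3P, 0.57 with HPP and -0.065 with PP, and RGS4 lies at -0.93 with I3P.

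I3P and HPP, which differ in their ring system, differed directly in 13 genes with the replicate block, 10 higher and 3 lower with I3P. THBS1 was higher with I3P by 0.71 in log2 (adjusted p = 0.00543), SECTM1 by 0.66 (adjusted p = 0.0202), RIMBP2 by 0.51 (adjusted p = 0.0202), CHODL by 0.42 (adjusted p = 0.0479) and SNX9 by 0.28 (adjusted p = 0.0479). SLC16A6, with the largest difference (0.91, adjusted p = 0.000232), and IGFBP1, a binding protein of insulin-like growth factors (0.54, adjusted p = 0.0161), were also higher and were named after their values were seen. Lower with I3P than with HPP were RWDD1 at -0.50 (adjusted p = 0.0202) and MYC at -0.30 (adjusted p = 0.0427). TIPARP was higher with I3P by 0.46 (adjusted p = 0.0479, 95% interval 0.28 to 0.64). The other AHR target genes did not pass, with differences of 0.425 for CYP1B1 (adjusted p = 0.0775, 95% interval 0.25 to 0.61), and 0.39 for STC2 (adjusted p = 0.0939). The differences were 0.37 for SERPINB2 (adjusted p = 0.283, 0.13 to 0.61), 0.30 for AHRR (adjusted p = 0.258, 0.12 to 0.48) and 0.08 for EREG (adjusted p = 0.838, -0.11 to 0.26). They were 0.16 for ABCG2, 0.16 for NFE2L2, 0.075 for CYP1A2, 0.03 for ALDH3A1, -0.11 for NQO1 and -0.16 for SLC7A5, the last 2 lower with I3P in 4 of 5 pairs. These intervals are not adjusted for the number of genes, so those that leave out 0 do not make a call. AHR was at -0.001 and ARNT at -0.08, and neither passed.

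As a list, AHR target genes were higher with I3P than with HPP by 0.18 ± 0.17 (log2, SD over 5 same-number pairs, 95% interval -0.031 to 0.39). The list was higher in 5 of 5 pairs, but barely in replicate numbers 1 (10.426 with I3P, 10.418 with HPP) and 3 (10.353 and 10.348). It was at 10.54 and 10.149 in number 2, 10.482 and 10.26 in number 4, and 10.376 and 10.097 in number 5. The exact 2-sided sign-flip p of 0.0625 is the smallest that 5 pairs can give. Camera gave an adjusted p of 0.00181 and 0.0215 with an estimated correlation. With the block it gave an adjusted p of 5.32e-05, but an adjusted p = 0.103 with the block and an estimated correlation. Over all genes 0 of the 12 members passed without the block and 1 with it, and adjusted over the list alone 0 and 5. NRF2 target genes were lower with I3P than with HPP, 15 of 16 below, by -0.12 ± 0.092 on average (95% interval -0.23 to -0.002, lower in 4 of 5 pairs, adjusted p = 5e-04). That call was lost with an estimated correlation (adjusted p = 0.135, and adjusted p = 0.0767 with the block as well). Over all genes 0 members passed, and TXNRD1 was at -0.37 and SLC7A11 at -0.33. Cell cycle genes were lower with I3P than with HPP (mean -0.069, lower in 5 of 5 pairs, adjusted p = 0.00581, and adjusted p = 0.835 with an estimated correlation). This call was lost without HPP replicate 3 (adjusted p = 0.148), I3P replicate 1 (0.0589) or I3P replicate 5 (0.393). Cytokine genes passed only with the block (mean 0.14, higher in 4 of 5 pairs, adjusted p = 0.369 without the block, 0.000877 with it, and adjusted p = 0.0767 with the block and an estimated correlation). Hypoxia genes did likewise (mean 0.062, higher in 4 of 5 pairs, adjusted p = 0.377, 0.0419, and adjusted p = 0.525 with the block and an estimated correlation), and the other lists passed in neither fit.

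Between I3P and HPP 384 genes had an unadjusted p under 0.05 without the block and 1099 with it, where 564 are expected by chance. Without the block limma called 0 genes, and the smallest adjusted p was 0.554, with RWDD1, SNX9 and PRKAG2 at the smallest p. The 13 calls with the block (10 higher, 3 lower) became 8 higher and 4 lower when the array medians were set equal. They became 4 without the arrays of number 3, 1 without those of number 5, 1 with the number as a random block and 1 when only the 10 arrays of these groups were fitted. The count was 2 without I3P replicate 2, 4 or 5, 3 without HPP replicate 2, and 4 without HPP replicate 1 or 4. It was 5 without HPP replicate 3 or I3P replicate 1, 7 without DMSO replicate 3 or 4, and 8 without DMSO replicate 1 or 2 or PP replicate 2, 3, 4 or 5.

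I3P and PP had the most calls of the 3 pairs. Without the block 9 genes were higher with I3P and 1 was lower. TIPARP was higher by 1.095 in log2 (adjusted p = 0.0113), SECTM1 by 1.035 (adjusted p = 0.013) and PRDM1 by 0.86 (adjusted p = 0.0113). CYP1B1 was higher by 0.84 (adjusted p = 0.013) and STC2 by 0.84 (adjusted p = 0.0188). The aldehyde dehydrogenase ALDH1A3 (0.67), LACC1, HK2 (0.45) and SNX9 were also higher, of which all but HK2 were named after their values were seen. TBR1, a transcription factor of cortical neurons, was lower with I3P at 8.85 against 9.57 with PP (log2 -0.72, adjusted p = 0.0113), while PP was at 0.33 against DMSO for it (adjusted p = 1). With the block 76 genes were higher and 26 lower, led by SLC16A6 (log2 1.52, adjusted p = 1.09e-07), THBS1 (1.21, adjusted p = 2.15e-06) and SERPINB2 (1.105, adjusted p = 5.1e-05). Lower with I3P were RGS4 (-0.80, adjusted p = 0.00297), SFMBT2 (-0.80, adjusted p = 0.0297) and TBR1. CPA4 (-0.61, adjusted p = 0.00203) and the noncoding RNA MIR503HG (-0.55, adjusted p = 0.0434) were lower too. SFMBT2 was dim, at 7.626 with I3P and 8.427 with PP, the first under the lowest probe set mean of 7.943. Signal over background cannot be seen there. Of the genes that passed against DMSO with the block, 44 were also higher and 7 also lower with I3P than with PP, against 0.371 and 0.03 expected of independent sets. The comparisons share the I3P arrays. AHR (-0.08) and ARNT (-0.046) did not pass.

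The AHR target list was higher with I3P than with PP by 0.48 ± 0.086 (log2, SD over 5 pairs, 95% interval 0.37 to 0.58, higher in 5 of 5). The camera adjusted p was 8.91e-13, and 1.04e-05 with an estimated correlation. Of the 12 members 3 passed over all genes and 6 adjusted over the list alone, and with the block 6 and 8. Those that passed over all genes only with the block were SERPINB2, AHRR (0.605, adjusted p = 0.303 without it and 0.0012 with it) and EREG (0.45, adjusted p = 0.757 and 0.0186). The members that passed in neither fit were at 0.295 for ALDH3A1, 0.24 for ABCG2, 0.19 for NFE2L2, 0.11 for NQO1, -0.005 for SLC7A5 and -0.05 for CYP1A2. Of other lists, INSIG1 (0.40, adjusted p = 0.975 without the block and 0.000599 with it) was higher and MYC (-0.29, adjusted p = 0.967 and 0.0124) lower with I3P. Cytokine genes passed with the block (adjusted p = 0.108 without it, 1.36e-05 with it, and adjusted p = 0.0151 with the block and an estimated correlation), at a mean of 0.23, and IL1B, PTGS2 and LIF were higher. Hypoxia genes passed with the block alone (mean 0.09, adjusted p = 0.101 without it, 0.00819 with it, and adjusted p = 0.286 with the block and an estimated correlation). Cell cycle genes were lower by camera (mean -0.066, 20 of 24 below, lower in 5 of 5 pairs, adjusted p = 0.0113, and adjusted p = 0.777 with an estimated correlation). So were respiratory chain genes (mean -0.073, 16 of 19 below, lower in 5 of 5 pairs, adjusted p = 0.0113, and adjusted p = 0.337 with an estimated correlation). In these lists 0 members passed by either adjustment. The cell cycle call was lost without I3P replicate 1 (adjusted p = 0.0762), I3P replicate 5 (0.344), PP replicate 2 (0.0683) or PP replicate 3 (0.301). The respiratory chain call was lost without I3P replicate 2 (0.0533) or PP replicate 4 (0.0681). The other lists passed in neither fit.

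Between I3P and PP 572 genes had an unadjusted p under 0.05 without the block and 1418 with it, where 564 are expected by chance. The 10 calls without the block became 0 without PP replicate 5, 4 without I3P replicate 1 and 5 without I3P replicate 5. They became 6 without I3P replicate 2 or 4 or PP replicate 4, and 16 with array weights. The 102 calls with the block became 53 without I3P replicate 5, 65 without PP replicate 3 and 66 without I3P replicate 2. They became 53 without the arrays of number 3, 50 without those of number 5, 73 with the number as a random block and 23 when only the 10 arrays of these groups were fitted.

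HPP and PP, which differ by a hydroxyl group on the ring, differed in 3 genes with the block, all higher with HPP. SERPINB2 was higher by 0.735 in log2 (adjusted p = 0.0256), TIPARP by 0.63 (adjusted p = 0.0131) and SLC16A6, named after its values were seen, by 0.61 (adjusted p = 0.0256). AHR (-0.08) and ARNT (0.04) did not pass. As a list, AHR target genes were higher with HPP by 0.295 ± 0.13 (log2, SD over 5 pairs, 95% interval 0.14 to 0.45, higher in 5 of 5). The camera adjusted p was 1.4e-09, and 6.63e-05 with an estimated correlation. Over all genes 0 members passed and 3 adjusted over the list alone, and with the block 2 and 7. CYP1B1, STC2 and AHRR did not pass, with 95% intervals of the difference of 0.24 to 0.60, 0.28 to 0.62 and 0.13 to 0.485 that are not adjusted for the number of genes. The other members, which did not pass either, were at 0.37 for EREG, 0.27 for ALDH3A1, 0.22 for NQO1, 0.15 for SLC7A5, 0.08 for ABCG2, 0.03 for NFE2L2 and -0.13 for CYP1A2. NRF2 target genes were higher with HPP by 0.11 ± 0.077 (log2, SD over 5 pairs, higher in 5 of 5, adjusted p = 0.00202). That call was lost with an estimated correlation (adjusted p = 0.259, and adjusted p = 0.161 with the block as well), without HPP replicate 1 (adjusted p = 0.0763) and without NQO1 and SLC7A11 (adjusted p = 0.111, a test added after the data were seen). SLC7A11 was at 0.54 and TXNRD1 at 0.36, with 0 members passing over all genes and 2 adjusted over the list alone. No other list passed between HPP and PP in either fit.

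Between HPP and PP 184 genes had an unadjusted p under 0.05 without the block and 595 with it, where 564 are expected by chance. Without the block limma called 0 genes. The smallest p were those of PRDM1 at 0.53, CIITA at 0.275 and AMOTL2 at 0.35 (adjusted p = 1). The 3 calls with the block became 0 without HPP replicate 1 or 3 or PP replicate 1 or 5, 5 without HPP replicate 2 or PP replicate 3 and 6 without I3P replicate 3. They became 0 without the arrays of number 3, 1 without those of number 5, 0 with the number as a random block and 0 when only the 10 arrays of these groups were fitted.

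**Figure D4:**
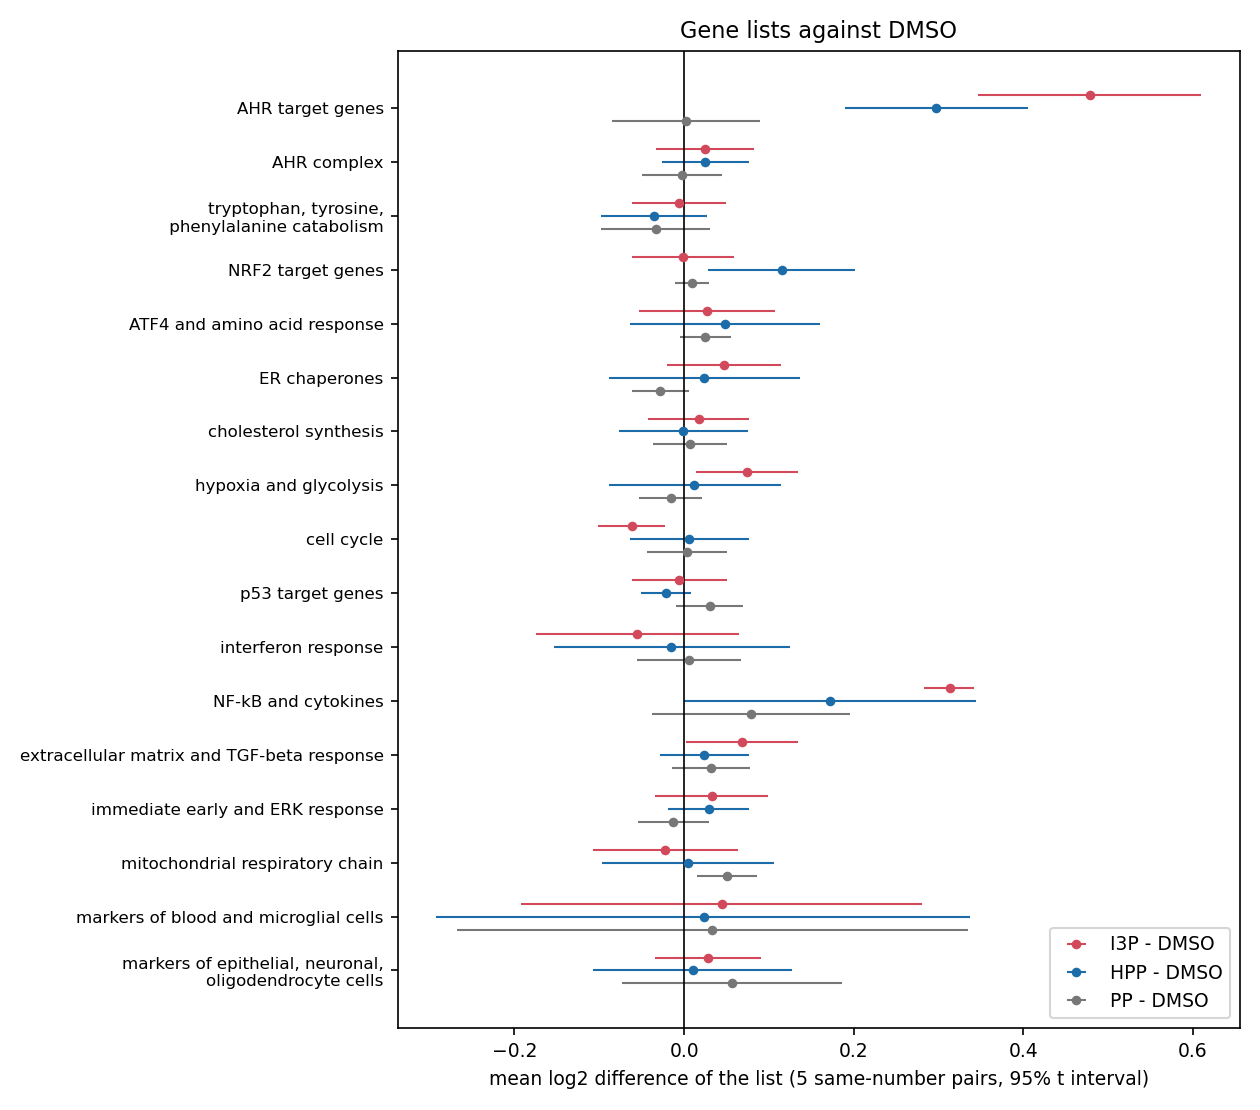
For each of the 17 gene lists (vertical axis) the points give the mean log2 difference from DMSO (horizontal axis) with I3P, HPP and PP, and the bars give 95% intervals over 5 same-number pairs. The AHR target list lies at 0.48 with I3P, 0.30 with HPP and 0.002 with PP, and the NRF2 target list at 0.12 with HPP and -0.001 with I3P.

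The genes that I3P changed were also followed in the other compounds. The 55 genes higher with I3P in the fit with the block had a median log2 change of 0.437 with I3P, 0.198 with HPP and 0.029 with PP. The 13 lower genes had medians of -0.405 with I3P, -0.136 with HPP and -0.048 with PP. All these genes were chosen against the same DMSO arrays, which alone moves HPP and PP toward the side of I3P. In a test added after the data were seen, 50 genes per direction were chosen in 3 replicate numbers and measured in the other 2. Their mean change was taken in each of 10 overlapping choices. The median of these means was 0.397 with I3P and 0.194 with HPP for raised genes, and -0.078 and 0.004 for lowered genes. All 5 genes called higher with HPP were among the 55 of I3P, against 0.0244 expected of independent sets. These comparisons share the DMSO arrays, which adds to the overlap. Across all 11282 genes, which are not independent replicates, the log2 changes with I3P and HPP correlated at r = 0.485, against 0.499 simulated with no effect and shared DMSO arrays. Changes with I3P and PP correlated at 0.336 (0.5 simulated), and those with HPP and PP at 0.47 (0.5 simulated). The covariance exceeded that simulated for I3P and HPP (0.00598 against 0.00505, a difference of 0.000927) and lay below it for I3P and PP (0.00422 against 0.00505, -0.000838) and for HPP and PP (0.00451 against 0.00506, -0.00055). With the DMSO arrays split between the compounds the correlations turned negative, at -0.282 and -0.274, -0.325 and -0.35, and -0.352 and -0.393. This split sets replicate numbers 1 and 2 against 3, 4 and 5. Simulated with no change and the shared deviations of the numbers (added after the data were seen) it gave -0.277 to -0.279 on average, so the negative sign needs no opposed response. The values of I3P and HPP lay within the 100 simulations, and those of the pairs with PP lay below all of theirs, for a reason not tested. The simulated noise was independent between genes, so the simulated range can be too narrow and nothing is concluded from these positions. With neither arrays nor replicate numbers shared (added after the data were seen) they were 0.121 and 0.095, -0.026 and -0.013, and 0.116 and 0.012.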

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

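Chosen only after the data were seen were the tests of HPP as part of the I3P response, of lists without single members (their bounds were set before their results), of NRF2 target genes without NQO1 and SLC7A11, of replicate numbers 1, 2 and 4 alone, and of counts without the block in splits that part all 5 pairs, while cyclic loess and an estimated correlation were settings fixed in advance whose bounds as tests of AHR and NRF2 target genes were set after those values were seen.

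AHR target genes were higher with I3P and with HPP. No single list member carries this, since with any member left out the adjusted camera p for HPP was at most 5.05e-08. After cyclic loess the adjusted camera p for HPP was 2.76e-10. That step was run on values already normalised by quantiles, so it tests only the scaling that this had left and cannot exclude scaling in general. That HPP gives part of the I3P response was tested with genes chosen for I3P in 3 replicate numbers and measured in the other 2. Among raised and among lowered genes, the 50 with the smallest limma p against DMSO were taken. The mean change over the 50 genes was taken in each choice, and medians are over the choices. In 10 of 10 such choices, which overlap, the raised genes stood in the order I3P, HPP, PP, with medians of 0.397, 0.194 and 0.024. The genes were chosen for I3P, so its first place follows from the choice, and only HPP above PP bears on the question. The lowered genes also stood in this order from the lowest in 10 of 10, with medians of -0.078, 0.004 and 0.049, but with HPP they were above DMSO in 5 of the 10. On raised genes chosen for I3P, HPP above PP in each choice goes with HPP giving part of the I3P response. Such genes cannot show how strongly HPP acts on other genes. The hypothesis was found and tested on the same arrays. Whether AHR itself carries the response was not tested because no group here lacks the receptor.

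NRF2 target genes were higher with HPP. A single member does not account for this, since the largest adjusted camera p with any member left out was 0.000507 (without TXNRD1), nor do NQO1 and SLC7A11, which other lists hold, since without both it was 0.00169. List members that vary together could account for it, since with an estimated correlation and no block the adjusted p was 0.0642, while with the block as well it was 0.0268. Chance through members that vary together and a response to HPP cannot be told apart here, because these settings fall on different sides of the threshold and over all genes 0 members passed.

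Arrays of the same replicate number deviated together in all groups. After cyclic loess the median correlation of same-number arrays was 0.432. Cyclic loess was run on values already normalised by quantiles, so it tests only the scaling that this had left and cannot exclude scaling in general. Over numbers 1, 2 and 4 the median was 0.375. The deviations were taken from group means that include numbers 3 and 5, whose shifts thus reach the other arrays. Whether numbers 3 and 5 alone account for the pattern therefore cannot be told from this value. The genes that respond to I3P may be ones that vary more between cultures. The median SD over the 5 PP arrays of the 68 genes called with the block was 0.242. This lay above all 10000 random sets of genes of like level (percentile 100, highest 0.21). The sets were drawn gene by gene and do not keep genes that vary together, so the percentile is not calibrated. The PP arrays hold each number once, so this SD includes the numbers' deviations. Whether the 68 genes account for a correlation over all genes was not tested. The labels give no culture, day or batch for the numbers, and no biological explanation of the shared deviation was tested.

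Single arrays stood apart from the rest of their group in 19 of 160 tests over 40 named genes, where chance marks about 1 in 20 groups, which is 8. Of the 19, 11 lie on arrays of number 3 and 6 on arrays of number 5. None of 68 tests of list means and none of 12 tests of array measures did so. In log2 signal, STC2 was low at 9.992 in DMSO replicate 3 (others 10.352 to 10.45) and 10.543 in I3P replicate 3 (11.168 to 11.348). THBS1 was low at 7.629 in DMSO replicate 3 (8.795 to 8.983), 8.719 in I3P replicate 3 (10.006 to 10.211) and 7.646 in PP replicate 3 (8.753 to 8.955). MEST was low at 8.943 in DMSO replicate 3 (9.97 to 10.246), 8.336 in I3P replicate 3 (9.398 to 9.745) and 8.786 in PP replicate 3 (9.958 to 10.197). CPA4 was low at 8.99 in PP replicate 3 (9.964 to 10.172). SLC35F4 was high at 9.324 in DMSO replicate 3 (8.267 to 8.339) and AHRR at 9.545 in I3P replicate 3 (9.221 to 9.306). On arrays of number 5, LOXL3 was low at 9.037 with DMSO (9.368 to 9.478), NQO1 at 10.953 with PP (11.235 to 11.343), and EREG at 11.902 with I3P (12.315 to 12.465) and 11.359 with PP (11.85 to 12.025). There ALDH3A1 was high at 9.279 with HPP (8.714 to 8.825) and TBR1 at 9.835 with PP (9.461 to 9.568). NFE2L2 was low at 10.261 in I3P replicate 4 (10.472 to 10.552) and CHODL at 8.379 in I3P replicate 1 (8.626 to 8.72).

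Probe sets that were not among the genes tested also passed with the replicate block. Against DMSO, 4 probe sets with no gene symbol and 2 with several were higher with I3P (largest log2 0.73). Against PP, 3 with no symbol and 2 with several differed with I3P (largest log2 0.783), and in the other comparisons 0 did.

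Other splits of the arrays test whether chance can be excluded for a count of calls. For I3P against DMSO the real split, with 9 genes, was the only 1 of 100 drawn from 126 with as many, the highest other having 0. For I3P against PP it was likewise 1 of 100 (10 genes, highest other 1). Chance can be excluded for these 2 counts only against splits that ignore the replicate numbers, which pair the arrays. Only 16 splits part all 5 pairs, too few for a share under 0.05 (smallest 0.0625), and without the block the highest other among them was 0 for both. The 9 genes became 0 without DMSO replicate 2 or 5 or I3P replicate 2 or 4, 1 without DMSO replicate 4, 2 without I3P replicate 1 and 3 without DMSO replicate 1, I3P replicate 3, HPP replicate 4 or PP replicate 4. They became 4 without DMSO replicate 3 and 5 without I3P replicate 5. The 10 genes became 0 without PP replicate 5, 4 without I3P replicate 1, 5 without I3P replicate 5 and 6 without I3P replicate 2 or 4 or PP replicate 4. For HPP against DMSO, PP against DMSO, I3P against HPP and HPP against PP the real count was 0 (highest others 2, 2, 2 and 1). Any split has at least 0 genes, so 100 of 100 reach this count whatever the data, and the splits decide nothing there. With the block the real counts of the 16 splits were 68, 5, 13, 102 and 3 for I3P and HPP against DMSO, I3P against HPP, I3P against PP and HPP against PP, each reached by 1 split with a highest other of 0, and for PP against DMSO, where the real count was 0, all 16 had 0.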

How the results depend on the processing

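Chosen after the data were seen were the alternatives applied on top of the replicate block, the random block, the fits without the arrays of number 3 or 5, the list tests with the block and an estimated correlation or without NQO1 and SLC7A11, the responses with no number shared and the simulation of the split of DMSO arrays. For every change given here the cause was not tested, except that a stricter threshold and a fold limit cannot add calls by construction. The block widened the calls from 9 to 68 for I3P against DMSO, 0 to 5 for HPP against DMSO, 0 to 13 for I3P against HPP, 10 to 102 for I3P against PP and 0 to 3 for HPP against PP. As a random block it gave 38, 0, 1, 73 and 0. Only the arrays of the groups compared gave 3 genes for I3P against DMSO and 6 for I3P against PP without the block, and 20, 0, 1, 23 and 0 with it. An adjusted p under 0.01 left 0 and 0 without the block, and 38, 1, 2, 41 and 0 with it. A fold over 1.5 left 5 for I3P against DMSO without the block, and with it 20 for I3P against DMSO, 2 for HPP against DMSO, 3 for I3P against HPP and 20 for I3P against PP. Array weights gave 16 for I3P against PP without the block and 7 for I3P against HPP with it. For I3P against HPP with the block, all probe sets gave 8 and a trended, robust variance 23. For HPP against PP with it, a trended, robust variance gave 10, genes above the median level 6 and genes above the 25th percentile 5. Without arrays of number 3 the block gave 0 for HPP against DMSO, 4 for I3P against HPP, 53 for I3P against PP and 0 for HPP against PP. Without number 5 it gave 37, 2, 1, 50 and 1 in the order above. Leaving out single arrays gave 0 to 10 genes for I3P against DMSO and 0 to 12 for I3P against PP without the block, while the counts of 0 stayed 0. With the block it gave 44 to 84, 1 to 6, 2 to 10, 53 to 102 and 0 to 6 in that order, with PP against DMSO at 0. The other scalings moved no median over all genes by more than -0.0107, the largest for I3P against PP.

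Of 102 list tests 13 passed without the block, and 7 of them passed without any single array. Cell cycle genes in I3P against DMSO, against HPP and against PP lost the call with an estimated correlation (adjusted p = 0.818, 0.835 and 0.777), with the block as well (0.395, 0.159 and 0.286) and after cyclic loess (0.0627, 0.074 and 0.0686). With fry, which tests a list against no change and not against other genes and so is not the same test, the adjusted p was 0.791, 0.914 and 0.758. Against DMSO they also lost it with array weights (0.0686). Cytokine genes in I3P against DMSO lost it with an estimated correlation (0.818), and fry gave 0.791. NRF2 target genes lost it with an estimated correlation (0.0642 for HPP against DMSO, 0.135 for I3P against HPP, 0.259 for HPP against PP), and with the block as well (0.0767 and 0.161 for the pairs of compounds), and fry gave 0.224, 0.163 and 0.472. For HPP against PP they also lost it without NQO1 and SLC7A11 (0.111). Respiratory chain genes in I3P against PP lost it with an estimated correlation (0.337), with the block as well (0.286) and after cyclic loess (0.0686), and fry gave 0.218. AHR target genes in I3P against HPP lost it with the block and an estimated correlation (0.103). Over single arrays left out, the adjusted p of AHR target genes ranged from 1.18e-14 to 1.78e-11 for I3P and 6.57e-11 to 4.51e-07 for HPP against DMSO, 4e-04 to 0.0154 for I3P against HPP, 2.23e-13 to 7e-10 for I3P against PP and 8.62e-10 to 9.4e-07 for HPP against PP. For NRF2 target genes it ranged from 1.15e-06 to 0.00277 for HPP against DMSO, 1.51e-05 to 0.0132 for I3P against HPP and 0.00032 to 0.0763 for HPP against PP (HPP replicate 1). For cell cycle genes it ranged from 0.000205 to 0.639 against DMSO (DMSO replicate 3), 0.000158 to 0.393 against HPP (I3P replicate 5) and 0.00021 to 0.344 against PP (I3P replicate 5). The range was for cytokine genes with I3P against DMSO from 6.63e-05 to 0.639 (DMSO replicate 3), and for the respiratory chain in I3P against PP from 0.00625 to 0.0681 (PP replicate 4). The correlations of responses (I3P with HPP, I3P with PP, HPP with PP) reversed with split DMSO arrays (-0.282 and -0.274, -0.325 and -0.35, -0.352 and -0.393). That split removes the shared control but also sets numbers 1 and 2 against 3, 4 and 5. With no change simulated it gave -0.277 to -0.279 with the shared deviations of the numbers (lowest of 100 simulations -0.316) and -0.002 to 0 without them. Simulated noise that is independent between genes can make this range too narrow. With no number shared they were 0.121 and 0.095, -0.026 and -0.013, and 0.116 and 0.012. That of I3P with PP was 0.236 in genes above the median level. They ranged from 0.41 to 0.592, 0.254 to 0.474 and 0.379 to 0.622 over single arrays left out. Values of named genes were set against the fit without the block over all its settings, the replicate block among them. Of these values 3743 kept their direction and side of the threshold, 120 fell short of it and 65 newly passed. Another 93 changed direction while passing in neither setting. With the block these numbers were 3530, 264, 24 and 62, and 0 values changed direction where either setting passed. Of the lists that did not pass, 2429 values kept their direction and side, 49 newly passed and 186 changed direction while passing in neither setting. Signal over background cannot be seen in these values, so genes dimmer than the table's lowest mean of 7.943 were out of reach.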

Other observations

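The genes and groups in these paragraphs were chosen after their values were seen, with no test of enrichment, and all calls are from limma with the replicate block for I3P against DMSO. Of the genes named here only PRDM1 was among the 9 that passed against DMSO without the block. Several genes of secreted proteins rose, and others fell, such as CPA4 (-0.57) and NOV (-0.35). IGFBP1 (log2 0.72, adjusted p = 0.000144) and IGFBP3 (0.41, adjusted p = 0.00662), which bind insulin-like growth factors, both rose, and both were also higher with I3P than with HPP (0.54 and 0.39, adjusted p = 0.0161 and 0.0443). The proteases MMP1 (0.65, adjusted p = 1.57e-05) and PLAU, which encodes urokinase (0.28, adjusted p = 0.0446), rose beside the urokinase inhibitor SERPINB2. IL1RN, the antagonist of the interleukin-1 receptor, rose (0.42, adjusted p = 0.0388) beside IL1B. Each of these changes had the same direction in 5 of 5 same-number pairs, which largely follows from selection by the fit with the block.

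Regulators of transcription went in both directions. RUNX2 (0.33, adjusted p = 0.0383) and E2F7 (0.34, adjusted p = 0.0359) rose with PRDM1. ID1 (-0.26, adjusted p = 0.0299) and ID3 (-0.455, adjusted p = 0.000664), which block basic helix-loop-helix factors, MYC and MECOM (-0.295, adjusted p = 0.0383) fell. MYC and ID3 were also lower with I3P than with PP (-0.29 and -0.44).

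The replicate numbers carried large differences in several genes, given here as mean deviations from the group means in log2. Number 3 was low in FDCSP (-2.587), FGF7 (-1.748), IL1RN (-1.615), LIF (-1.33), IL6 (-1.305) and PTGS2 (-1.195), and high in PODXL (1.614) and SLC7A8 (1.408). Other genes parted numbers 1 and 2 from 4 and 5. NLRP13 was at -0.905 and -0.401 in the former and 1.041 and 1.018 in the latter. IL16 was at 1.051 and 0.463, and at -0.81 and -1.126. The number took up a median of 93% of the sum of squares within groups in the cytokine list, 85.2% in the hypoxia list, 81.5% in the ATF4 list, 80.3% in the extracellular matrix list and 76.1% in the AHR target list, against 54% over all genes.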
